A study of Homo sapiens with 8 samples.

How the data were processed

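Total RNA of 8 monocyte preparations, isolated from fresh blood of 4 healthy donors by negative magnetic selection, was biotin-labelled and hybridised to Affymetrix arrays, per the labels' protocols. The groups were untreated cells (UT, 4 arrays) and cells treated with 25 ng/ml interferon gamma (IFNg, 4 arrays), both given as 24 hours. The donor number served as replicate number. The deposited table holds log2 values, 1 per probe set and array, and the submitters' processing notes name GCRMA (background correction, normalization and summary per probe set) and limma, with no version, settings or role. The log2 scale was read from the deposited values themselves, which share 1 lowest value, 2.33, on all 8 arrays and reach 15.1.

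Of 54675 probe sets in the table, 62 controls were left out. Per the platform annotation, updated by gene identifier to the names of human assembly GRCh38.p14, 41091 had 1 gene, 1801 several genes and 11721 none listed. Identifiers matched for 41037 of the first kind, and 54 kept the name in the annotation. Probe sets with several genes or none were not used, and genes of the Y chromosome, XIST and TSIX were left out. Of the 19740 genes with a probe set, 10511 had more than 1, and each gene took the probe set with the highest mean over the 8 arrays. A gene was tested when at least 4 of the 8 arrays had a log2 value of at least 4, which left 9019 genes. Of 4212 genes with more than 1 probe set past this filter, 3 had probe sets called in opposite directions: NUMA1, PTPRO and C6orf89, of which NUMA1 was called as rising and PTPRO as falling. Probe sets of a gene could also differ in the size of change. Examples among named genes are CGAS (-0.02 to 1.57), APOL2 (0.46 to 3.43), SOCS1 (1.44 to 5.51) and SAMD4A (3.14 to 6.62). Further examples are CXCL2 (-2.73 to -0.59), IL1R1 (-4.55 to -1.71) and THBS1 (-5.94 to -2.25). Where all arrays of 1 group lay under 4, a called change is given as a bound: the mean of the brighter group against 4 on each array of the dimmer one, with the adjusted p of the fit. The bound is on group means and takes no account of the spread between donors, so single donors can lie below it. Where only part of a group lay under 4, the fitted change includes values near background, and the number of arrays at or above 4 is given with it.

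IFNg was compared with UT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without a donor block since the processing notes name none, and p values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors are those of the moderated fit. Adjusted p values of genes are from this limma fit unless said otherwise, and tests are two-sided unless said otherwise. The arrays are paired because both arrays of a number come from the same donor. Deviations from the group means correlated between both arrays of a donor across genes with coefficients of 0.338 to 0.675, and 4 of 4 IFNg arrays correlated best with the UT array of their own donor. The first principal component held 60.4% of the variance and the second 18.9%. Fits with the donor as a block are therefore given where they change a call or move a count by over 1.5 times. Fits with arrays left out had no donor block, so calls lost in them are those of the unpaired fit.

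Before the data were examined, 38 gene lists were fixed (pathways, cell type markers and quality markers), of whose 759 memberships 688 had a probe set. The 32 lists with at least 5 tested genes were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, with the correlation estimated per list and with fry beside it. Calls adjusted over the list alone use the same p values with Benjamini-Hochberg inside the list. Also fixed beforehand was the rule for naming genes: the 12 largest rises and 12 largest falls among called genes that moved the same way in all 4 donors, up to 4 called members of each list by size and up to 2 called against the list's majority, up to 2 of the brightest members where none was called, and 16 genes of interest. This gave 141 genes with a probe set, of which 138 were tested and 121 called. Genes without a probe set of their own in the table used here are not reported.

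The fits were tested on simulated data with 9019 genes in 4 against 4 arrays. Genes given a log2 change of 1 were recovered in 56% of cases, of 2 in 96%, and of 3 or 4 in 100%. Of 193 calls 8 were false, and 0 of 20 lists without change were called. Simulated genes were independent of each other and had no donor effect, unlike the real data. The simulation therefore does not show how often lists of correlated genes are called without a change.

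The alternatives were the donor as a block, no filter on dim genes, a filter at a log2 value of 6, a floor at 4, quantile normalization, median centring, the mean of a gene's probe sets, limma with trend and robust options, array weights, leaving out each array and each donor, the estimated correlation, fry, and an adjusted p of 0.01. All 35 splits of the 8 arrays into 4 and 4 were fitted. Chosen after the data were seen were the tests of symbol families (Fisher's exact test, one-sided), of neighbouring genes (10000 shuffles of the calls over the gene order of the assembly named above, one-sided) and an exact two-sided permutation test of each list's mean level. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for these and the figures.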

Results

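Messenger RNA levels were measured on 8 expression arrays of monocytes from the blood of 4 healthy donors. For 24 hours, cells of each donor were either left untreated (UT, 4 arrays) or treated with interferon gamma (IFNg, 4 arrays) at 25 ng/ml. Each donor thus gave 1 array to each group. Interferon gamma is the cytokine by which T and NK cells activate mononuclear phagocytes. The deposited values were distributed alike on the arrays, which normalization in GCRMA also brings about. The median log2 value of a probe set lay between 2.50 and 2.52, and the upper quartile between 5.47 and 5.56. At the lowest value of 2.33 sat 33.3% to 33.9% of probe sets. The number of arrays limits the precision of every value given.

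The comparison of IFNg with UT arrays asked which transcripts of blood monocytes differ after a day of interferon gamma. The T cell-attracting chemokines CXCL9, CXCL11 and CXCL10, the immune checkpoint ligand CD274 (PD-L1) and the itaconate-producing enzyme ACOD1 were among the genes with the largest rises, while the interleukin-1 receptors IL1R2 and IL1R1, the secreted ribonuclease RNASE1 and the matrix protease MMP9 were among those with the largest falls. CXCL9 rose by 7.96 on the log2 scale (SE 1.53), from a mean of 5.78 ± 3.57 (SD, n = 4) to 13.74 ± 0.29 (SD, n = 4). IL1R2, a decoy receptor for interleukin-1, fell by 6.25 (SE 0.61), from 9.52 ± 0.98 (SD, n = 4) to 3.27 ± 1.03 (SD, n = 4), with 1 of 4 IFNg arrays at or above a log2 value of 4, the limit used here for a measurable signal. Of 9019 genes tested, 1898 passed an adjusted p of 0.05 in limma, of which 1017 rose and 881 fell, and 1887 of them moved the same way in all 4 donors. Calls need the groups to lie apart on these same arrays, so that agreement is no independent support. A change of at least 2-fold was reached by 1075 genes, of which 637 rose and 438 fell. With the donor as a block the count was 3146, of which 1551 rose and 1595 fell, and 1881 genes were shared. The count fell to 1189 without IFNg replicate 1, to 933 without IFNg replicate 3 and to 1047 without UT replicate 3, and to 763, 955 and 216 without both arrays of donors 1, 2 and 3. The 2-fold count fell to 686 without IFNg replicate 3, and to 641, 680 and 209 without donors 1, 2 and 3.

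**Figure D1:**
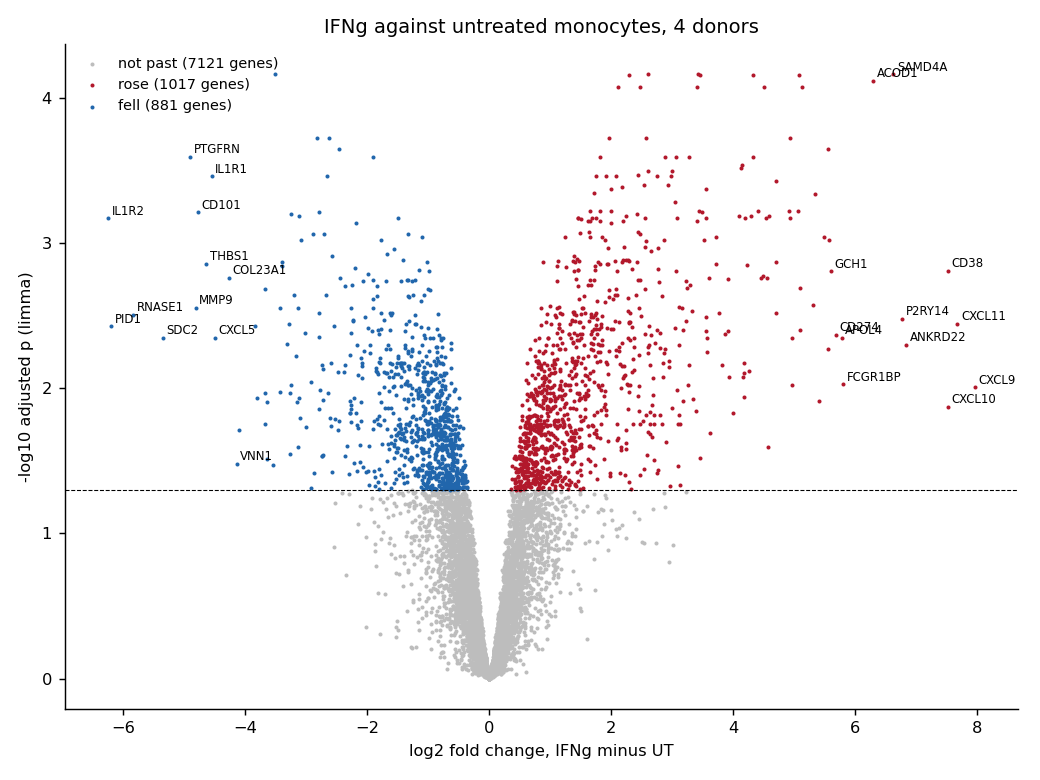
Change of each of the 9019 tested genes (log2 fold change, IFNg minus UT, horizontal) against -log10 of its limma adjusted p (vertical); the dashed line marks an adjusted p of 0.05 and the 12 largest rises and 12 largest falls are named. The 1017 genes that rose reach 7.96 (CXCL9) and the 881 that fell reach -6.25 (IL1R2). With values under the limit raised to 4, CXCL9 is at 7.41 and IL1R2 at -5.32, behind PID1 at -5.84 and RNASE1 at -5.77.

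Among the 12 largest rises, CXCL11 rose by 7.67 (SE 1.12), CXCL10 by 7.52 (SE 1.57) and the NAD-consuming ectoenzyme CD38 by 7.52 (SE 0.90). UT levels of these genes were at or above the limit on 2 of 4 arrays for CXCL9 and CXCL10 and on 1 of 4 for CXCL11 and CD38, so their fitted changes include values under the limit. With those values raised to 4, CXCL9 rose by 7.41, CXCL11 by 6.81, CXCL10 by 7.08 and CD38 by 6.48. CD274 rose by 5.68 (SE 0.87, adjusted p = 0.00428) and was measurable on 3 UT arrays. GCH1, which starts tetrahydrobiopterin synthesis, rose by 5.60 (SE 0.67, adjusted p = 0.00157) and was measurable on all 8 arrays. ACOD1 rose by 6.29 (SE 0.36, adjusted p = 7.63e-05), with 1 of 4 UT arrays at or above the limit, and by 5.76 with values under it raised to 4. The RNA-binding protein gene SAMD4A was under the limit on all 4 UT arrays and was at least 53.7-fold higher in IFNg arrays (adjusted p = 6.89e-05). ANKRD22 rose by 6.83 (SE 1.10), the UDP-glucose receptor gene P2RY14 by 6.77 (SE 0.97) and APOL4 by 5.78 (SE 0.90), with 3, 2 and 2 of 4 UT arrays at or above the limit, and by 6.54, 5.97 and 5.0 with values under it raised to 4. In that setting APOL4 lay below SOCS1 (5.49) and GBP1 (5.40), which are not among the 12. The probe set assigned to FCGR1BP rose by 5.79 (SE 1.10), with 3 of 4 UT arrays at or above the limit, but this pseudogene is a near copy of the Fc receptor gene FCGR1A, so the source of its signal is uncertain. The probe set of FCGR1A itself was too dim to test, at 2.33 in every UT array and 4.42 ± 0.63 (SD, n = 4) in IFNg arrays.

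Among the 12 largest falls, PID1 fell by 6.20 (SE 0.92), RNASE1 fell by 5.83 (SE 0.82) and MMP9 fell by 4.81 (SE 0.66), with 2, 3 and 2 of 4 IFNg arrays at or above the limit. The matrix glycoprotein THBS1 fell by 4.64 (SE 0.54, adjusted p = 0.0014) and IL1R1, the signalling interleukin-1 receptor, fell by 4.55 (SE 0.38, adjusted p = 0.000348), both measurable on all 8 arrays. Genes under the limit on all 4 IFNg arrays were the syndecan SDC2, at least 18.5-fold lower, PTGFRN, at least 14.7-fold lower, CD101, at least 14.5-fold lower, the neutrophil chemokine CXCL5, at least 11.8-fold lower, and the collagen COL23A1, at least 6.79-fold lower. These bounds are on group means. The least negative donor differences of these genes were -2.63, -4.10, -3.76, -2.82 and -2.44 on the log2 scale, in that order. With values under the limit raised to 4, CXCL5 changed by -3.56 and COL23A1 by -2.76, less than EREG (-3.81), which is not among the 12. Membership of the 12 thus depends on values under the limit. The pantetheinase gene VNN1 fell by 4.14 (SE 1.11, adjusted p = 0.0333), with 3 IFNg arrays at or above the limit, a call lost without any 1 of 6 of the 8 arrays (adjusted p 0.0519 to 0.0872).

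**Figure D2:**
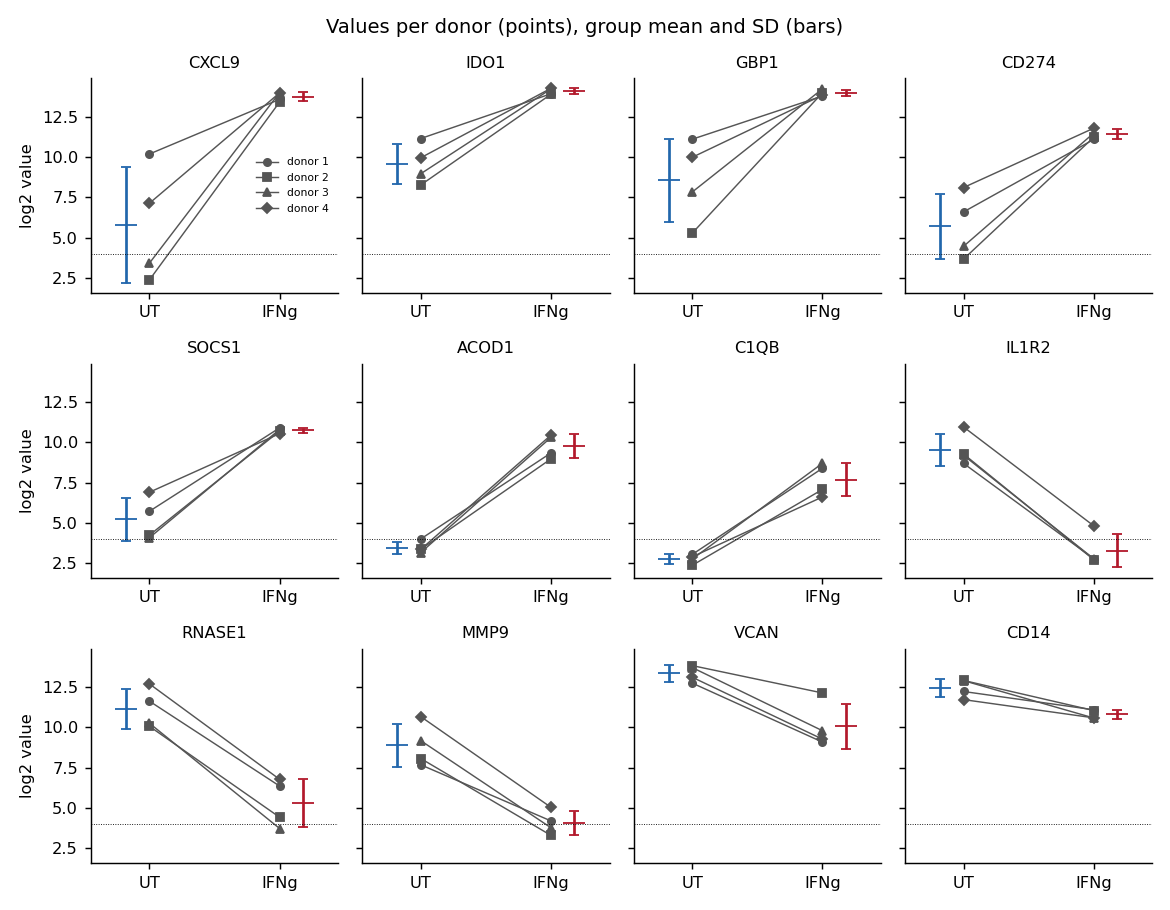
Log2 values of 12 genes in UT and IFNg arrays, with a line per donor and the group mean with its SD (n = 4) beside; the dotted line is the limit of 4. CXCL9 lies between 2.39 and 10.2 in UT arrays and at 13.74 ± 0.29 in IFNg arrays, and RNASE1 is lower in the IFNg array of each of the 4 donors.

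Interferon-response genes were tested as 3 lists. In the list of 40 tested type I interferon signature genes, 35 rose and 0 fell, with a median change of 2.66, and 38 rose when adjusted over the list alone. RSAD2 (viperin) rose by 5.55 (SE 0.91), IFITM1 by 5.09 (SE 0.77), IFI27 by 4.70 (SE 0.39) and IFIT2 by 4.69 (SE 0.66), with 3, 3, 1 and 4 of the UT arrays at or above the limit. With values under the limit raised to 4, IFI27 rose by 3.82. All 5 tested guanylate-binding proteins, GTPases of host defence, rose, with a median of 4.17, and 5 did so adjusted over the list alone. GBP1 rose by 5.40 (SE 1.10), GBP4 by 4.93 (SE 0.48) and GBP5 by 4.17 (SE 0.75). Among 28 JAK-STAT and IRF regulators, 14 rose, 2 fell and 12 did not pass, and adjusted over the list alone 16 rose and 2 fell. The feedback inhibitor SOCS1 rose by 5.49 (SE 0.58, adjusted p = 0.000909), BATF2 by 4.59 (SE 0.44, with 1 UT array at or above the limit, and by 4.22 with values under it raised to 4), JAK2 by 3.16 (SE 0.43) and the transcription factor IRF1 by 3.05 (SE 0.45). IFNGR1, the ligand-binding chain of the interferon gamma receptor, fell by 1.02 (SE 0.18, adjusted p = 0.00669), and STAT5B fell by 0.58 (SE 0.17, adjusted p = 0.0462), a call lost without any 1 of 7 arrays (adjusted p 0.0618 to 0.123). IFNGR2 had a change of -0.16 (SE 0.14, adjusted p = 0.461). The camera test with a preset correlation called these 3 lists at adjusted p 9.74e-19, 0.000141 and 1.24e-05. With an estimated correlation the adjusted p was 0.471, 0.471 and 0.385, past the threshold for none of them.

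The list levels on single arrays differed between donors. The median level of the type I signature list was 7.62, 5.57, 8.19 and 7.89 in UT arrays of donors 1 to 4 and between 9.90 and 10.79 in IFNg arrays. Guanylate-binding proteins had UT medians of 11.1, 6.70, 7.07 and 9.53 and IFNg medians between 12.1 and 12.6. In these lists the medians of UT arrays lay further apart than those of IFNg arrays, while for JAK-STAT and IRF regulators the medians lay closer, between 8.53 and 8.83 in UT arrays and between 9.60 and 10.09 in IFNg arrays, and the mean levels further apart, between 7.94 and 8.59 and between 9.58 and 9.71. The donors' changes differed in size, from 2.67 to 8.70 for GBP1, which was measurable on all 8 arrays.

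**Figure D3:**
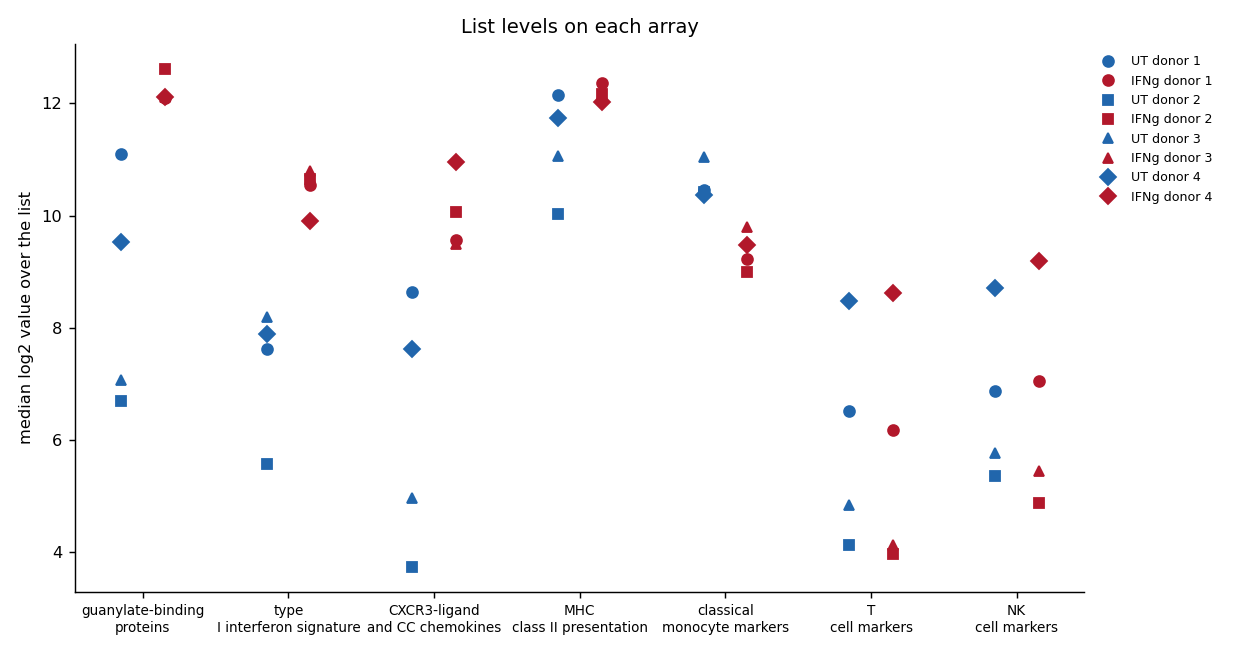
Median log2 value over 7 gene lists on each array, with symbols for donors and colours for groups. The UT arrays spread from 6.70 to 11.1 in guanylate-binding proteins while IFNg arrays lie between 12.1 and 12.6, and T and NK cell markers are highest in both arrays of donor 4.

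Antigen presentation and costimulation genes were tested as 3 lists. Of 20 tested MHC class I presentation genes, 9 rose, 0 fell and 11 did not pass, and adjusted over the list alone 11 rose and 1 fell. NLRC5, the transactivator of MHC class I genes, rose by 3.08 (SE 0.60), the peptide transporter subunits TAP2 and TAP1 by 3.22 (SE 0.47) and 2.19 (SE 0.25), and the immunoproteasome subunit PSMB9 by 2.45 (SE 0.41). Of 16 MHC class II presentation genes, 2 rose and 14 did not pass, both adjusted over all genes and adjusted over the list alone, with a median change of 0.88. HLA-DOB rose by 2.35 (SE 0.53, adjusted p = 0.0177), with 2 of 4 UT arrays at or above the limit, and the transcription factor RFX5 by 1.65 (SE 0.44, adjusted p = 0.0318), a call lost without any 1 of 5 arrays (adjusted p 0.0512 to 0.0918). CIITA, the class II transactivator, had a change of 0.83 (SE 0.49, adjusted p = 0.271). It was higher in 3 donors, by up to 1.54, and lower in donor 4, with a difference of -0.92. Of 18 costimulation and checkpoint genes, 8 rose and 10 did not pass, and 10 rose adjusted over the list alone. SLAMF7 rose by 4.18 (SE 0.84), PDCD1LG2 (PD-L2) by 3.91 (SE 0.48) and CD80 by 3.77 (SE 0.53), the last 2 with 1 UT array at or above the limit, and by 2.91 and 2.80 with values under it raised to 4. In camera the class I, class II and costimulation lists had an adjusted p of 3.63e-05, 0.0144 and 0.00479. With an estimated correlation the adjusted p was 0.471, 0.483 and 0.471.

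Chemokines were tested as 2 lists. In the list of 8 tested CXCR3-ligand and CC chemokines, 4 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. CCL8 was under the limit on all UT arrays and at least 23.7-fold higher in IFNg arrays, while CCL22 fell by 2.73 (SE 0.70, adjusted p = 0.0287), with 3 IFNg arrays at or above the limit, a call lost without any 1 of 5 arrays (adjusted p 0.0534 to 0.0760). The camera adjusted p of this list was 0.0420, and 0.0799 with the donor as a block, 0.471 as an adjusted p with an estimated correlation, and 0.0586 to 0.339 without any 1 of 6 arrays. Its adjusted p was also 0.0523 with the filter on dim genes at 6, 0.0840 with array weights and 0.179 without that filter, where the list median was 0.03 in place of 3.33. Of 7 neutrophil-attracting and early inflammatory chemokines, 4 fell and 0 rose, likewise adjusted over the list alone. Beside CXCL5, CXCL2 fell by 2.73 (SE 0.55, adjusted p = 0.0121). CXCL8 (interleukin-8) fell by 2.11 (SE 0.47, adjusted p = 0.0169), a call lost without IFNg replicate 3 (adjusted p = 0.0543). CXCL3 fell by 3.26 (SE 0.84, adjusted p = 0.0283), lost without any 1 of 5 arrays (adjusted p 0.0539 to 0.0854). The list's camera adjusted p was 0.0210, the adjusted p with an estimated correlation 0.483, and without any 1 of 4 arrays it was 0.0520 to 0.169. With the filter on dim genes at 6 it was 0.0606.

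In the list of 17 tested inflammatory cytokines, 7 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone. TNFSF10 (TRAIL) rose by 3.34 (SE 0.68), TNF by 2.60 (SE 0.42) and TNFSF13B (BAFF) by 2.30 (SE 0.32). The growth factor genes EREG and VEGFA fell by 3.81 (SE 0.77) and fell by 1.81 (SE 0.31). IL1B had a change of -1.17 (SE 0.79, adjusted p = 0.332), and IL10 was too dim to test, at 2.44 ± 0.22 (SD, n = 4) in UT arrays and 2.33 in every IFNg array. The list's camera adjusted p was 0.0367, with 0.483 as the adjusted p with an estimated correlation and 0.0590 to 0.0858 without any 1 of 3 arrays. Of 26 cell death and inflammasome genes, 12 rose, 2 fell and 12 did not pass, as they did adjusted over the list alone. The cytosolic DNA sensor AIM2 rose by 5.09 (SE 0.65), with 2 UT arrays at or above the limit, and by 4.56 with values under it raised to 4. The apolipoproteins L APOL1, APOL3 and APOL2 rose by 4.10 (SE 0.39), 3.87 (SE 0.59) and 3.43 (SE 0.32), and the TRAIL receptor TNFRSF10B fell by 1.57 (SE 0.17). NLRC4 fell by 1.88 (SE 0.53, adjusted p = 0.0408), lost without any 1 of 6 arrays (adjusted p 0.0634 to 0.109). The camera adjusted p was 0.000141, and the adjusted p with an estimated correlation 0.385.

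**Figure D4:**
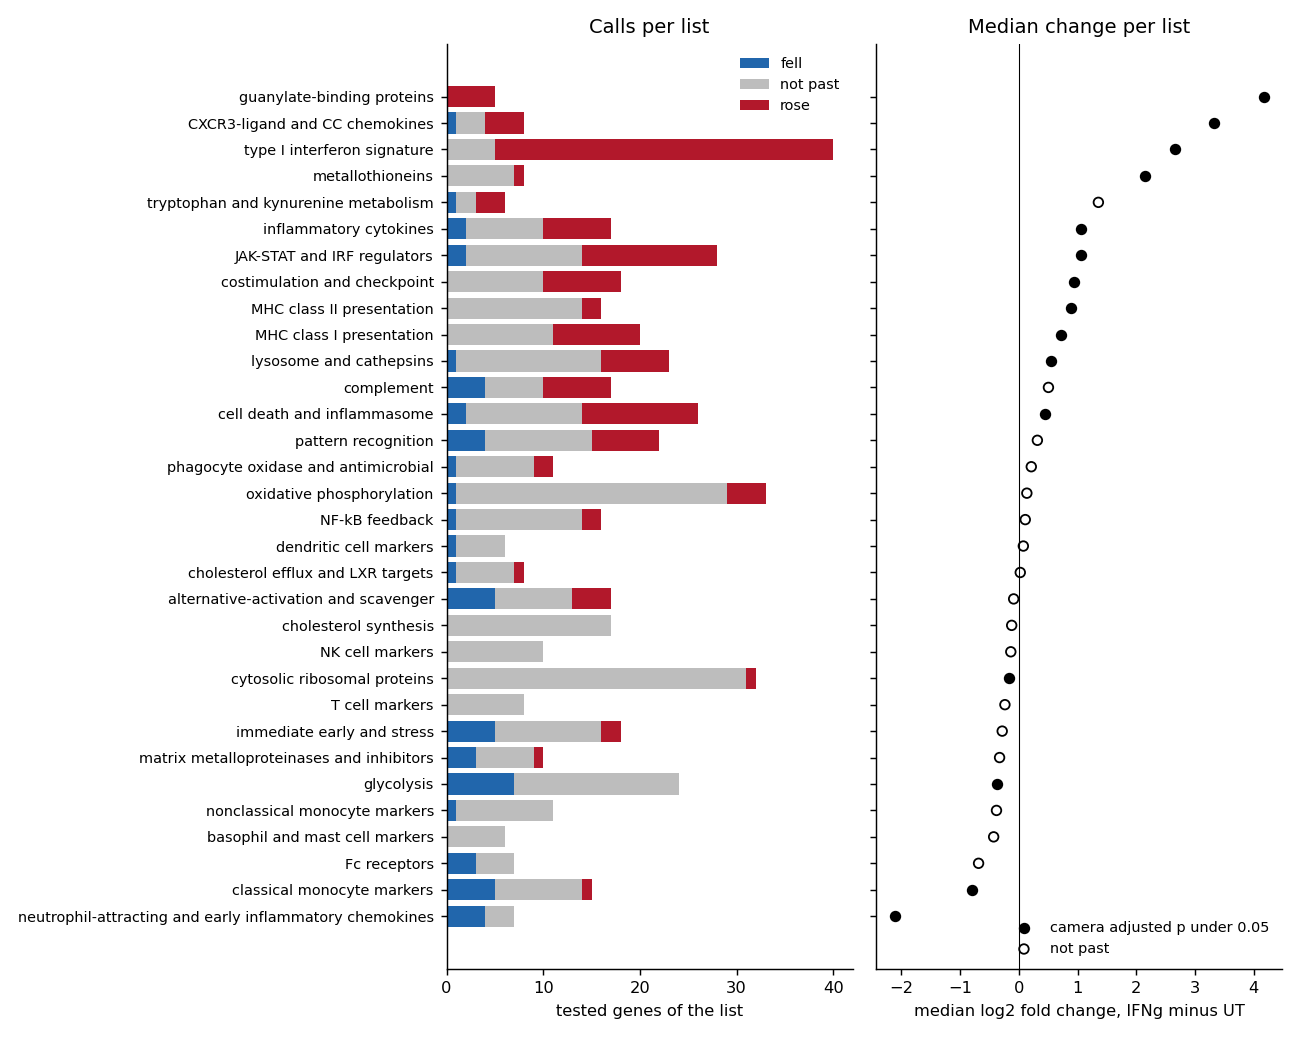
For the 32 gene lists with at least 5 tested genes, the number of genes that rose, fell or did not pass (left) and the median log2 fold change, IFNg minus UT (right), with filled points where the camera adjusted p with a preset correlation is under 0.05. The 15 filled lists run from a median of -2.11 for neutrophil-attracting and early inflammatory chemokines to 4.17 for guanylate-binding proteins.

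Lists of metabolism, lysosome, metal binding and ribosome were tested in the same way. Of 24 glycolysis genes, 7 fell and 0 rose, with 8 falls adjusted over the list alone and a median of -0.38. ENO2 fell by 1.81 (SE 0.50, adjusted p = 0.0359) and the glucose transporter gene SLC2A1 fell by 1.50 (SE 0.38, adjusted p = 0.0257), with 2 IFNg arrays at or above the limit. Each of these calls was lost without any 1 of 4 arrays (adjusted p 0.0788 to 0.0890 and 0.0622 to 0.0784). GPI and ALDOC fell by 0.87 (SE 0.25) and fell by 0.84 (SE 0.21), calls lost without any 1 of 6 and of 5 arrays (adjusted p 0.0572 to 0.116 and 0.0517 to 0.0784). The glycolysis list had a camera adjusted p of 0.00679 and 0.483 as the adjusted p with an estimated correlation. Of 23 lysosome and cathepsin genes, 7 rose, 1 fell and 15 did not pass, and 8 rose and 1 fell adjusted over the list alone. CTSL rose by 2.85 (SE 0.53) and CTSK fell by 1.81 (SE 0.36), the list's camera adjusted p was 0.00679, and the adjusted p with an estimated correlation was 0.471. Of 8 genes of the metallothionein list, which also holds the zinc exporter gene SLC30A1, only SLC30A1 passed over all genes, with a rise of 0.97 (SE 0.28, adjusted p = 0.0428) that was lost without any 1 of 6 arrays (adjusted p 0.0594 to 0.111) and with the mean of probe sets (adjusted p 0.151). Adjusted over the list alone 7 rose. The list median was 2.14, with a camera adjusted p of 0.0117, of 0.0541 without IFNg replicate 4, and 0.483 as the adjusted p with an estimated correlation. Cytosolic ribosomal proteins had a median of -0.17 over 32 genes, a camera adjusted p of 0.0117 and an adjusted p of 0.483 with an estimated correlation. RPLP2 alone passed among them and went the other way, rising by 0.48 (SE 0.13, adjusted p = 0.0303), a call lost without any 1 of 5 arrays (adjusted p 0.0522 to 0.0878), and 0 passed adjusted over the list alone. Oxidative phosphorylation genes had 4 rises and 1 fall among 33, the same adjusted over the list alone, and a camera adjusted p of 0.259. NDUFA9 rose by 1.46 (SE 0.29) and UQCRB fell by 0.76 (SE 0.12). Cholesterol synthesis genes had 0 calls among 17, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.419). Cholesterol efflux and LXR targets had 1 rise and 1 fall among 8, also adjusted over the list alone, with a median of 0.02, a mean of 0.00 and a camera test in the downward direction (adjusted p = 0.782).

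Markers of monocyte subsets were tested as 2 lists. Of 15 classical monocyte markers, 5 fell, 1 rose and 9 did not pass, likewise adjusted over the list alone. The proteoglycan VCAN fell by 3.27 (SE 0.64), the leukotriene pathway gene ALOX5AP fell by 3.16 (SE 0.65), CD93 fell by 2.73 (SE 0.49) and the endotoxin co-receptor CD14 fell by 1.61 (SE 0.29, adjusted p = 0.00763), while PLBD1 rose by 1.91 (SE 0.40). S100A12 fell by 2.08 (SE 0.56, adjusted p = 0.0349), a call lost without any 1 of 7 arrays (adjusted p 0.0618 to 0.0896). The camera adjusted p of the list was 0.0195, 0.0592 without UT replicate 3, and 0.471 as the adjusted p with an estimated correlation. Of 11 nonclassical monocyte markers 1 fell (camera adjusted p = 0.557), and 2 rose and 2 fell adjusted over the list alone. The fractalkine receptor gene CX3CR1 fell by 1.80 (SE 0.55), with an adjusted p of 0.0495, of 0.0619 with the donor as a block, of 0.0532 with the mean of probe sets, and of 0.0544 to 0.125 without any 1 of 7 arrays.

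Other response lists did not pass the camera test with the preset correlation, whose adjusted p is given with the counts of each list. In fry, the complement, tryptophan and kynurenine, phagocyte oxidase and antimicrobial, and Fc receptor lists passed (adjusted p 0.0328, 0.005, 0.0165 and 0.0342). Pattern recognition did not (fry adjusted p = 0.0640). Of 17 complement genes, 7 rose, 4 fell and 6 did not pass (adjusted p = 0.129), with 8 rises and 4 falls adjusted over the list alone. The convertase component CFB rose by 5.07 (SE 0.47), the C1 inhibitor SERPING1 by 4.97 (SE 0.94) and C1QC by 4.69 (SE 0.54), with 1, 4 and 3 of the UT arrays at or above the limit, and C1QB was at least 12.9-fold higher. With values under the limit raised to 4, CFB rose by 4.31 and C1QC by 4.32. The receptors C5AR1 and CR1 fell by 2.06 (SE 0.34) and fell by 1.50 (SE 0.27). Of 6 tryptophan and kynurenine genes, 3 rose and 1 fell (adjusted p = 0.133), likewise adjusted over the list alone. IDO1, which degrades tryptophan, rose by 4.49 (SE 0.55) to 14.07 ± 0.19 (SD, n = 4), IDO2 by 5.57 (SE 0.59) with 2 UT arrays at or above the limit, and the tryptophanyl-tRNA synthetase WARS1 by 2.75 (SE 0.23), while KYAT3 fell by 0.81 (SE 0.16). Of 11 phagocyte oxidase and antimicrobial genes, 2 rose and 1 fell (adjusted p = 0.138), with 5 rises and 2 falls adjusted over the list alone. The risen genes were ACOD1 and GCH1, and the metal transporter gene SLC11A1 fell by 3.16 (SE 0.53). Of 7 Fc receptors, 3 fell (adjusted p = 0.133), with 1 rise and 4 falls adjusted over the list alone. FCER1A fell by 3.42 (SE 0.67), with 3 IFNg arrays at or above the limit, and the near-identical FCGR2B and FCGR2C, whose signals are uncertain, fell by 0.87 (SE 0.22) and fell by 0.69 (SE 0.20), calls each lost without any 1 of 6 arrays (adjusted p 0.0504 to 0.0849 and 0.0671 to 0.101). Of 22 pattern recognition genes, 7 rose and 4 fell (adjusted p = 0.243), with 8 rises and 5 falls adjusted over the list alone. TLR7 rose by 2.89 (SE 0.71, adjusted p = 0.0235), with 3 UT arrays at or above the limit, CGAS by 1.57 (SE 0.34, adjusted p = 0.0158) and TREM1 fell by 2.75 (SE 0.71, adjusted p = 0.0293). These calls were lost without any 1 of 3 arrays, without IFNg replicate 3 and without any 1 of 4 arrays (adjusted p 0.0574 to 0.0687, 0.0541, and 0.0707 to 0.0807). Another CGAS probe set past the filter on dim genes had a change of -0.02.

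In the alternative-activation and scavenger list, 4 genes rose and 5 fell among 17, likewise adjusted over the list alone, and the median of -0.09 and mean of -0.48 stood against an upward camera direction at an adjusted p of 1.00. The scavenger receptor MSR1 rose by 3.93 (SE 0.72), with 3 UT arrays at or above the limit, and the transglutaminase TGM2 was at least 5.81-fold higher. The coagulation factor F13A1 fell by 3.67 (SE 0.72), with 3 IFNg arrays at or above the limit, and VSIG4 was at least 3.22-fold lower. The mannose receptor MRC1 had a change of -0.81 (SE 1.31, adjusted p = 0.708), with 2 donors higher and 2 lower. UT replicate 4 stood at 11.40 against 4.80 to 6.02 in the other UT arrays, and with arrays left out the change ranged from -1.58 to 0.84. Of 10 matrix metalloproteinases and inhibitors, 3 fell and 1 rose (camera adjusted p = 0.133, fry adjusted p = 0.0183), likewise adjusted over the list alone. MMP19 fell by 3.25 (SE 0.62) with 3 IFNg arrays at or above the limit, and MMP25 rose by 2.46 (SE 0.31) with 1 UT array there, and by 2.27 with values under it raised to 4. Of 18 immediate early and stress genes, 5 fell and 2 rose (adjusted p = 0.448), with 6 falls and 2 rises adjusted over the list alone. FOS fell by 3.43 (SE 0.47), EGR1 fell by 2.17 (SE 0.49) and IER3 fell by 1.82 (SE 0.33), whereas the mRNA-decay factor ZFP36 rose by 1.11 (SE 0.14) and the chaperone HSP90AA1 by 0.81 (SE 0.16). Of 16 NF-kB feedback genes, 2 rose and 1 fell (adjusted p = 0.604), with 1 rise and 1 fall adjusted over the list alone. TNFAIP2 rose by 2.44 (SE 0.25) and REL fell by 0.96 (SE 0.19).

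Markers of other blood cells were checked in the same arrays. T cell markers had 0 calls among 8 genes and NK cell markers 0 among 10, also adjusted over the list alone (camera adjusted p = 0.844 and 0.941), and both lists were highest in donor 4. The T cell list had a median level of 8.47 in the UT array and 8.62 in the IFNg array of that donor and between 3.97 and 6.52 in the other 6 arrays. Without donor 4 the count of called genes was 1802, but only 1431 of the 1898 genes called with all arrays were among them. IL7R had a change of -1.50 (SE 1.18, adjusted p = 0.401) and CD247 of -0.78 (SE 1.12, adjusted p = 0.663), with 0.0119 and 0.0196 as adjusted p with the donor as a block. Dendritic cell markers had 1 fall among 6 genes, FCER1A, also adjusted over the list alone, and a median of 0.08 against a mean of -0.78 and a downward camera direction (adjusted p = 0.653). Basophil and mast cell markers had 0 calls among 6, also adjusted over the list alone (adjusted p = 0.447). The remaining lists had under 5 tested genes and no list test. In them the B cell gene BANK1 rose by 3.59 (SE 0.44), with 1 UT array at or above the limit (2.52 with values under it raised to 4), the Notch ligand JAG1 by 2.65 (SE 0.29), and PCNA by 0.84 (SE 0.24, adjusted p = 0.0421), the last lost without any 1 of 6 arrays (adjusted p 0.0626 to 0.117). Of 13 B cell markers with a probe set, BANK1 was the 1 that passed the filter on dim genes, so no change of B cells can be read from it. The platelet genes PPBP and PF4 had changes of -1.35 (SE 0.94, adjusted p = 0.345) and -1.18 (SE 0.94, adjusted p = 0.411), and the neutrophil gene LTF of -1.80 (SE 1.70, adjusted p = 0.492), with 3 UT and 3 IFNg arrays at or above the limit. With the donor as a block their adjusted p was 0.0147, 0.00962 and 0.0181. Of the erythroid genes, HBD had a change of 0.37 (SE 0.58, adjusted p = 0.692), with 2 UT and 3 IFNg arrays at or above the limit.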

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

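The tests of the differences between untreated donors and of the T and NK cell markers in this part were chosen after the values had been seen. Of 330 groups of 4 arrays examined, 19 held an array whose gap to the nearest other array took up more of the group's range than the 95% limit of Dixon's test, and chance alone gives about 1 in 20, or 16.5.

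In UT arrays, CD38 was highest in donor 1 at a log2 value of 6.71, against 2.44 to 2.92 in the others. CD80 was highest in donor 4 at 4.58, against 2.69 to 2.71. For CD38 and CD80 the other donors lay under the limit for a measurable signal, so the size of the gap is uncertain. IL7R was highest in donor 4 at 11.30, against 7.61 to 8.0. STAT5B was highest in donor 2 at 8.92, against 8.62 to 8.67. IL1R1 was lowest in donor 3 at 9.25, against 10.08 to 10.17. FCER1A was lowest in donor 1 at 7.57, against 8.57 to 8.70. JUN was lowest in donor 1 at 8.33, against 9.42 to 9.60. The complement list median was lowest in donor 2 at 6.12, against 7.61 to 7.66, and that of classical monocyte markers was highest in donor 3 at 11.04, against 10.36 to 10.45.

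In IFNg arrays, donor 4 stood apart in 7 genes. IL1R2 was highest there at 4.82, against 2.72 to 2.78, ALOX5AP at 9.47, against 6.41 to 6.93, HSP90AA1 at 12.65, against 12.40 to 12.42, and PLBD1 at 11.70, against 11.38 to 11.41. For IL1R2 the other donors lay under the limit for a measurable signal. SERPING1 was lowest there at 11.67, against 12.18 to 12.21, APOL1 at 9.06, against 9.63 to 9.70, and S100A12 at 6.71, against 7.71 to 7.92. APOL3 was highest in donor 3 at 11.59, against 10.91 to 11.00, and IFI27 lowest in donor 2 at 7.27, against 7.95 to 8.08. The guanylate-binding protein median was highest in donor 2 at 12.61, against 12.10 to 12.12.

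T and NK cell markers were highest in both arrays of donor 4: by a median of 3.17 over the mean of the other donors in UT arrays and 3.88 in IFNg arrays. All tested genes shifted there by a median of at most 0.0481, so no shift shared by all genes remained in the deposited values. Normalization in GCRMA aligns the arrays, so this median cannot decide on array-wide scaling before it. Lymphocytes carried over past the negative selection, which is meant to remove them, remain a candidate explanation. Of the 18 tested markers, 94.4%, 17 genes, were highest in that donor in both groups, against 17.1% of all genes. The donor was picked by the UT median of these same markers, so this share is no independent support. Markers also moved together, with an estimated correlation of 0.951 in the T cell list and 0.848 in the NK cell list. Among abundant transcripts, GNLY stood at 10.71 and 10.94 in the UT and IFNg array of that donor and at 7.43 to 9.04 in the other 6 arrays, and NKG7 at 9.59 and 10.11 against 6.30 to 8.62. The T and NK lists share 0 tested genes, 9 of the 18 were at or above the limit in all 6 arrays of the other donors, and no biological explanation was tested.

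Type I interferon signature genes varied between untreated donors, with list medians 2.62 apart on the log2 scale in UT arrays and 0.89 apart in IFNg arrays. The wide UT range came from the array of donor 2, at 5.57. UT arrays of donors 1, 3 and 4 lay between 7.62 and 8.19, closer together than the IFNg arrays. The median of all tested genes had a range of 0.0870 in UT arrays, a closeness that normalization in GCRMA brings about in any case. It therefore cannot decide on array-wide scaling. A ceiling of the signal in IFNg arrays stays open: among the 15 members with an IFNg mean under 10 the median ratio of the SD in IFNg arrays to that in UT arrays was 0.766, against 0.350 over all members and 0.930 over all genes. Interferon gamma from carried-over lymphocytes may contribute but cannot be told apart from differences between donors with 4 UT arrays: the UT array with the most T and NK signal lay at -0.30 from the highest UT array, and the highest, of donor 3, had a T and NK median of 5.07 against 8.48. For guanylate-binding proteins the UT arrays of donors 1 and 4, with the highest T and NK medians (6.63 and 8.48), also had the highest levels (11.1 and 9.53), while the IFNG transcript, chosen after its values were seen, was under the limit on all 4 UT arrays, highest of them in donor 4 (3.10 against 2.33 to 2.54), and above it in the IFNg array of donor 4 (4.88), and no biological explanation was tested.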

How the results depend on the processing

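No alternative in this part was chosen after the results were seen. The 1898 called genes became 3146 with the donor as a block and 935 without the filter on dim genes, where 19740 genes were tested, and 673 passed an adjusted p of 0.01. The 1075 genes past 2-fold became 591 without the filter. With 1 array or 1 donor left out, these counts ranged from 216 (without donor 3) to 1982 (without UT replicate 4) and from 209 to 1169. Rises made up 53.6% of calls, and 64.1% without donor 1, 72.7% without donor 3 and 63.7% at an adjusted p of 0.01. Under the filter at 6, the floor at 4, quantile normalization, median centring, the mean of probe sets, trend and robust options, and array weights, 1616 to 2778 genes were called, within 1.5 times. The 15 called lists became 0 in camera with an estimated correlation per list (2 at an unadjusted p under 0.05, lowest adjusted p 0.385), where the estimates for these 15 lists were 0.0564 to 0.782 against the preset 0.01. Fry called 18, of which 13 were among the 15 (without MHC class II presentation and metallothioneins). Its 5 further lists had a fry adjusted p of 0.005 to 0.0342. They were tryptophan and kynurenine metabolism, phagocyte oxidase and antimicrobial, Fc receptors, complement, and matrix metalloproteinases and inhibitors. The other alternatives called 11 to 16. The complement list passed camera without the filter and with the mean of probe sets, and matrix metalloproteinases and inhibitors with the filter at 6.

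Named genes kept their direction in each alternative refitted with all 8 arrays. Without the filter on dim genes, with more genes tested, 49 named genes lost the call. Among them were CXCL9, CXCL10, GBP1, NLRC5, SLAMF7, SERPING1 and TNFSF10. Calls of 0 to 4 named genes were lost under the donor block, the filter at 6, the floor at 4, quantile normalization, median centring, the mean of probe sets, trend and robust options, or array weights. Their calls were not counted at an adjusted p of 0.01. PTPRO was the 1 called gene that passed in the opposite direction in any alternative, at 0.56 with the mean of probe sets against -1.06, as its probe sets disagree. Of 121 called named genes, 29 lost the call without at least 1 array, as did 5 of the 15 lists. These fits had no donor block, and leaving out 1 array also broke a pair. In limma with the donor as a block and all 8 arrays, CX3CR1 (adjusted p = 0.0619) was the 1 called named gene that lost the call. Other genes that lost it without an array had a limma adjusted p from 0.00135 (CXCL8) to 0.0466 (FCGR2C) with the block. Among them were NLRC4 at 0.0037, VNN1 at 0.00472 and S100A12 at 0.00574. The donor block changed no call of a named gene or list other than those given with the results. With the filter at 6, 124 of 138 named genes and 30 of 32 lists had a value.

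Uncalled results turned in direction. For the alternative-activation and scavenger list the camera test was upward with a median of -0.0881, and downward with the donor block (-0.0881), without the filter (-0.0681), with the filter at 6 (-0.29), with quantile normalization (-0.13) and with the mean of probe sets (-0.54), and the median ranged from -0.76 to 0.39 with arrays left out. The NK cell marker test, downward with a median of -0.14, turned upward with the filter at 6 (0.0505) and with median centring (-0.18), and the median ranged from -0.79 to 0.63. The T cell marker median ranged from -1.46 to 0.43. With arrays or donors left out, changes ranged from -1.73 to 0.0281 for CD247, -0.83 to 0.54 for GNLY, -1.20 to 0.0766 for NKG7, -0.44 to 0.27 for FCGR3B, -0.0122 to 0.78 for HBD, -0.77 to 0.66 for IL3RA, -0.79 to 0.0796 for GATA2 and -1.58 to 0.84 for MRC1. Leaving out arrays leaves fewer samples, and dropping the filter adds genes near the lowest value, where signal over background limits the test. For the other changes the cause was not tested.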

Other observations

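The tests of symbol families, of neighbouring genes and of list mean levels in this part were chosen after the data had been seen, the neighbour test with its bounds set before it was run. Of the families of genes that share the letters of their symbol, 3 held more rises than chance in 580 tests of at least 5 tested members, against 1017 rises among 9019 genes. All 5 apolipoproteins L rose (log2 changes 2.23 to 5.78, Fisher's exact test, adjusted p = 0.00524), as did all 5 guanylate-binding proteins (adjusted p = 0.00524). Of 11 tested symbols that begin with PSMB, which are 10 proteasome beta subunit genes and the antisense RNA PSMB8-AS1, 7 rose and 0 fell (adjusted p = 0.00962). Besides the immunoproteasome subunit PSMB9, already given, PSMB10 rose by 2.13 (SE 0.35) and PSMB8 by 1.53 (SE 0.23), which are also subunits of the immunoproteasome. PSMB3 rose by 1.57 (SE 0.22), PSMB2 by 1.01 (SE 0.21), PSMB4 by 0.72 (SE 0.18) and PSMB1 by 0.54 (SE 0.14), and these subunits belong to both the constitutive and the immunoproteasome. PSMB5, PSMB6 and PSMB7 had changes of 0.44 (SE 0.16), 0.40 (SE 0.22) and 0.38 (SE 0.16), with adjusted p of 0.0763, 0.232 and 0.130, and of 0.0244, 0.0445 and 0.0755 with the donor as a block. All 7 called subunits were higher in 4 of 4 donors. The counts of rises in these 3 families were the same under the floor at 4, quantile normalization and median centring. With the donor as a block 9 of the 10 beta subunits rose and PSMB8-AS1 fell. Other families did not pass, among them IFI with 5 rises among 8 (adjusted p = 0.109) and TRIM with 9 among 25 (adjusted p = 0.126).

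Called genes under the limit on every array of 1 group numbered 40 that rose and 37 that fell. At least 4-fold changes were found for 12 of the former and 11 of the latter. Such genes were tested only if all 4 arrays of the other group reached the limit. Their separation is thus set by the filter, and the counts do not measure how often it leads to a call. Besides those already given, and chosen after their values were seen, the succinate receptor SUCNR1 was at least 10.6-fold higher, BCL2L14 at least 11.1-fold, SEPTIN4 at least 10.6-fold, GRIN3A at least 9.58-fold and C1QA, a chain of complement C1q, at least 4.57-fold. THBD (thrombomodulin) was at least 6.37-fold lower and TFPI (tissue factor pathway inhibitor) at least 5.06-fold lower, and both restrain coagulation.

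Called genes that moved the same way lay next to each other along the chromosomes more often than by chance placement. There were 200 neighbouring pairs of tested genes that both rose, against a mean of 114 and a highest value of 148 in 10000 shuffles (p = 0.0001, the smallest the permutation can give), and 133 pairs that both fell, against a highest value of 118. Families of one symbol alone are argued against as the whole account, since 166 of the risen pairs joined different families, against a highest value of 143. Shared regulation of neighbours is a hypothesis that stays open, as do overlapping transcripts and probes shared between them, which were not tested. There were 15 runs of 4 or more genes. Runs that rose held GBP3, GBP1, GBP2, GBP4 and GBP5 on chromosome 1, the 5 apolipoproteins L on chromosome 22, JAK2, PLGRKT, CD274, PDCD1LG2 and RIC1 on chromosome 9, SP110, SP140, SP140L and SP100 on chromosome 2, and PARP9, DTX3L, PARP14 and HSPBAP1 on chromosome 3. A run on chromosome 4 that fell held CXCL5, CXCL3, CXCL2, LOC105377276 and EREG.

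Over all splits, which ignore the pairing of arrays by donor, the real grouping stood far apart in the count of called genes. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, reached 1898 genes, and the highest other split gave 3. The same held for the 2-fold count, at 1075 against 3, again in 1 of 35 splits. For the lists, 1 of 35 splits reached 15, but the highest other split gave 14, and the highest of the other splits that also part all 4 donors gave 12, while those 14 came from splits that keep 2 donors whole. The other splits called 2 to 14 lists with the preset correlation, so the real grouping stands out by 1 list. The arrays are paired, and 8 of the 35 splits part all 4 donors, the real one among them. The others of these 8 called 0 genes. As 8 splits are too few for a share under 0.05, they cannot exclude chance for any of these counts with the pairing kept.

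The mean level of a list was also compared between groups by an exact two-sided permutation test, which in 4 against 4 arrays cannot go below p = 0.0286. Of 32 lists, 16 reached that value, among them 12 of the 15 called by camera, with an adjusted p of 0.0571, so that 0 passed after adjustment. The type I signature list mean was 2.72 higher in IFNg arrays and higher in 4 of 4 donors, and the classical monocyte marker mean fell by 1.07 and was lower in 4 of 4 donors.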
